A study of Mus musculus with 8 samples.

How the data were processed

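RNA was measured by sequencing in 8 libraries of mouse myeloid progenitors. Per the labels, hematopoietic stem and progenitor cells from C57BL/6J fetal livers at embryonic day 14.5 were infected with a virus carrying Trim27 or with a control virus carrying GFP, and myeloid progenitors were then sorted. There were 4 libraries per group. Polyadenylated RNA was converted to double-stranded DNA, and libraries were made with a transposase-based kit, per the labels' protocols.

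The authors deposited 1 table of raw read counts per gene symbol with a column for each library. The submitters' processing notes name bcl2fastq, HISAT2, featureCounts and the genome build NCBIM37. Their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table listed 33435 named genes. It held 1 line with no gene name, which had 0 counts and was left out. No count was listed in any library for 18338 of the genes. Total counts were 9257889 to 10747794 in the GFP libraries and 10551137 to 16366571 in the Trim27 libraries. Small counts were mostly even. In GFP replicate 1, 255 genes had a count of 1, 872 had a count of 2 and 155 had a count of 3. Of the counts from 1 to 10, 68.4% to 72% were even in the GFP libraries and 64.7% to 67% in the Trim27 libraries. Counting both reads of a pair would give this, and the deposited counts would then overstate the number of independent fragments.

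Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default rule of filterByExpr (minimum count 10, minimum total count 15), which left 11040 genes. Libraries were scaled by TMM, and every CPM given here is relative to the TMM-scaled library size. Differences between the Trim27 and GFP groups were tested 2-sided by edgeR's quasi-likelihood test with robust estimation and no covariate, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Standard errors were taken from the fitted log2 fold change and its F statistic. Such an SE can be too small where a group holds few or no counts. A gene with no count in any library of 1 group was given as at least N-fold different, against a floor of 3 counts over the 4 libraries of that group. A gene with 1 to 3 counts in a group was given as a ratio with its 95% counting interval. These floors and intervals cover counting error only, and they treat each count as an independent fragment. If both reads of a pair were counted, the intervals are too narrow and the fold bounds too high.

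The named genes followed a rule fixed in advance. They were Trim27, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 3 log2 CPM and no overlap between the groups (symbols of predicted genes and cDNA clones were passed over, and so was Trim27), up to 4 members of each gene list with the smallest p past the threshold (up to 2, as values only, where none passed), and 7 myeloid transcription factors whatever their p, namely Spi1, Cebpa, Cebpe, Irf8, Gfi1, Klf4 and Runx1. One gene that the rule picked is not reported here. The title of the series speaks of myeloid master genes, so the authors may have chosen some of these on the same samples.

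The 26 gene lists were fixed at the same time. They cover myeloid transcription factors, primary granule genes, late neutrophil genes, monocyte genes, tissue macrophage markers, dendritic cell and MHC class II genes, myeloid cytokine receptors, erythroid genes, megakaryocyte genes, mast cell, basophil and eosinophil genes, stem cell and multipotent progenitor genes, B cell markers, T and NK cell markers, hepatocyte markers, endothelial and stromal markers, interferon-stimulated genes, NF-kB targets, JAK-STAT components and targets, cell cycle genes, p53 targets, immediate early and heat shock genes, unfolded protein and integrated stress response genes, cholesterol synthesis, glycolysis, cytosolic ribosomal proteins and mitochondrially encoded genes. The 22 lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists. Adgre1, Epb42 and Mpig6b were looked up under the older symbols of the table, Emr1, Epb4.2 and G6b.

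The alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile factors and library size only in the same fit, no filter or a filter of 10 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom without and with quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, leaving out each library, a fold change above 1.5 by glmTreat, an adjusted p under 0.10, camera with an estimated correlation, and fry. Further alternatives were chosen after seeing the data. They were genes with a mean of at least 6 log2 CPM only, an offset that removes the trend of each library with transcript length, the same offset fitted on those abundant genes, and halved counts. Transcript lengths, gene overlaps and gene order came from the GENCODE M21 annotation, which is on another build than the authors' files, so no coordinates are given. A median length over the protein-coding transcripts of a gene was found for 10594 of the tested genes (95.96%).

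The same code was tested on simulated data drawn from the gene means of the GFP group and the sizes of the 8 libraries. The draw used a common dispersion, treated genes as independent and changed 200 of 9304 tested genes. The code recovered 30% of the genes changed 1.25-fold, 94% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold. Of 170 calls, 9 were false. A simulated shift of the cell cycle list was called by camera, and 0 of the 21 other lists were. In the real data 85.53% of tested genes passed the threshold, so the simulation does not show how scaling or false calls behave there. Because its genes were independent, it also does not test the preset correlation.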

Results

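The transcriptomes of sorted fetal liver myeloid progenitors were compared between 4 libraries of cells infected with a virus carrying Trim27, a tripartite motif protein with ubiquitin ligase activity, and 4 libraries of cells infected with a GFP control virus. Total counts were 9832190, 10448007, 9257889 and 10747794 in GFP replicates 1 to 4, and 14781518, 15204026, 16366571 and 10551137 in Trim27 replicates 1 to 4. Between 11131 and 11850 genes were detected in the GFP libraries, and between 12962 and 13283 in the Trim27 libraries. The larger number was not a matter of depth alone, since Trim27 replicate 4 had 12962 genes at 10551137 counts and GFP replicate 4 had 11131 genes at 10747794 counts. Cytosolic ribosomal protein genes took 26.62% ± 0.0685 of the counts in the GFP group and 18.84% ± 0.345 in the Trim27 group (SD, n = 4 each).

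Libraries of a group were close to each other. The correlation of log2 values across genes, which are not independent replicates, was 0.9903 to 0.9951 over the 12 pairs within groups and 0.8104 to 0.8317 over the 16 pairs between groups. The chi-square per degree of freedom of the counts was 2.64 to 10.95 within groups and 117.6 to 146.8 between groups. Trim27 replicate 1 gave the highest values within groups, 6.65 to 10.95 against the other Trim27 libraries. If each fragment had been counted as a pair of reads, the range within groups would be 1.32 to 5.47, still above sampling noise. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values below measure only the spread between these libraries, which may be technical.

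The comparison asks which genes change when Trim27 is added to myeloid progenitors, and whether myeloid regulators are among them. Trim27 rose from 180.5 ± 8.52 CPM in the GFP group to 292.7 ± 18.4 CPM in the Trim27 group (SD, n = 4 each), a log2 fold change of 0.70 (SE 0.05), and each Trim27 library lay above every GFP library. A change of this size was ordinary for its abundance. Among genes from 6 to 8 log2 CPM, 86.5% passed the threshold. Their log2 fold changes had a median absolute value of 0.50 and an SD of 0.76. The rise of Trim27 therefore does not by itself show that the virus raised it. The regulators Spi1, Runx1, Egr1 and Irf8 rose as well, while Cebpe and Gfi1 fell. Ribosomal protein genes fell almost without exception. At an adjusted p below the threshold 5249 genes rose and 4193 fell, and many of low abundance were listed in 1 group only. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p for Trim27 was 7.4e-13.

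Of 11040 genes tested, 9442 (85.53%) passed the threshold, of which 5249 rose and 4193 fell. At least 2-fold changes were found for 3455 of the genes that rose and 1769 of those that fell. The groups did not overlap for 8911 genes (80.72%), against 2.857% by chance. With library size alone as scaling the calls were 6277 rises and 3106 falls, a share of rises of 66.9% against 55.59%, because that scaling moved the median log2 fold change of all tested genes from 0.14 to 0.44. The Trim27 value also depended on 1 setting chosen after seeing the data. With the trend of each library on transcript length removed it was 0.09 (adjusted p = 0.123), whereas it was 0.70 with the trend of abundant genes removed. The balance of calls also turned with the length trend removed, to 4243 rises and 4749 falls. It was 5659 rises and 3175 falls with the trend of abundant genes removed.

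The 12 largest rises were all genes with no count in any GFP library. They included Htra3, a secreted serine protease (at least 434-fold higher, 36.0 ± 3.30 CPM in the Trim27 group), Sfrp4, a secreted antagonist of Wnt signalling (at least 428-fold), P2ry2, a nucleotide receptor (at least 292-fold), March8, a membrane ubiquitin ligase (at least 283-fold), and Slc24a3, a sodium, potassium and calcium exchanger (at least 266-fold). Cryz, Car8, App, Spp1, Plek2, Laptm4b and Usp20 followed, at least 211-fold to at least 253-fold higher. Cryz overlaps Tyw3 on the opposite strand, so its counts are uncertain. The 12 largest falls were led by Kctd21 (40.4 ± 2.67 CPM in the GFP group, at least 851-fold lower), Cpxm1 (at least 785-fold), Atp4a, a subunit of the gastric proton pump (at least 631-fold), and Stard8 (at least 471-fold). Hfe, a regulator of iron uptake, Rbp4, a carrier of retinol, and Lta, a cytokine of the tumour necrosis factor family, had no count in any Trim27 library and were at least 401-fold to at least 438-fold lower. Depdc7 (log2 fold change -9.49), Kifap3 (-8.23), Tigd3 (-8.08), Echdc3 (-8.06) and Aldh1l1 (-8.01) kept 4 counts each over the Trim27 libraries. Their fitted values rest on these few counts, so no SE is given for them. With a floor of 6 counts, for fragments counted as pairs, the bound for Htra3 would be at least 217-fold.

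**Figure D1:**
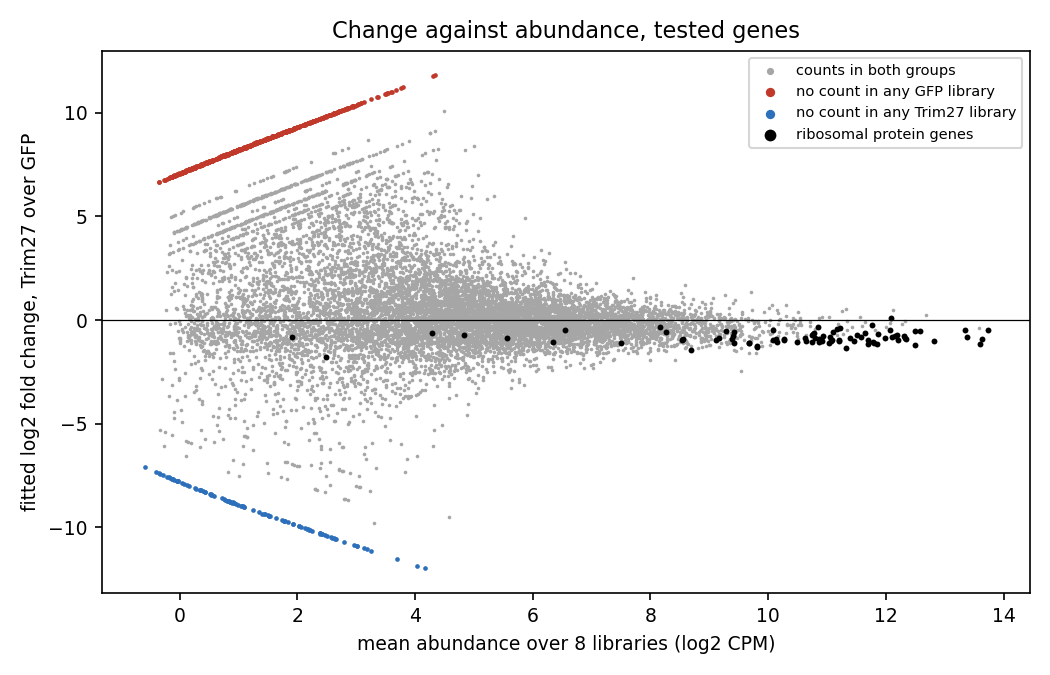
Each point is 1 of the 11040 tested genes, with its mean abundance over the 8 libraries in log2 CPM on the horizontal axis and its fitted log2 fold change of Trim27 over GFP on the vertical axis. Genes with no count in any GFP library (532, red) and in any Trim27 library (101, blue) lie along the edges at low abundance, where fitted values are not bounds, and the ribosomal protein genes (black) lie mostly below 0 at high abundance.

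The size of the changes depended on abundance. The standard deviation of the log2 fold changes was 4.25 among genes under 2 log2 CPM, 3.47 from 2 to 4, 1.60 from 4 to 6, 0.76 from 6 to 8, 0.57 from 8 to 10, and 0.47 at 10 or more. No count was listed in any GFP library for 532 tested genes and in any Trim27 library for 101. All of them had a mean under 6 log2 CPM. The change also followed transcript length, with a median log2 fold change of -0.74 for genes under 500 bases, -0.25 from 500 to 1000, 0.14 from 1000 to 2000, 0.45 from 2000 to 4000, 0.65 from 4000 to 8000 and 0.55 at 8000 or more. Among genes with a mean of at least 6 log2 CPM the median was 0.00 from 2000 to 4000 bases and -0.07 from 4000 to 8000.

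**Figure D2:**
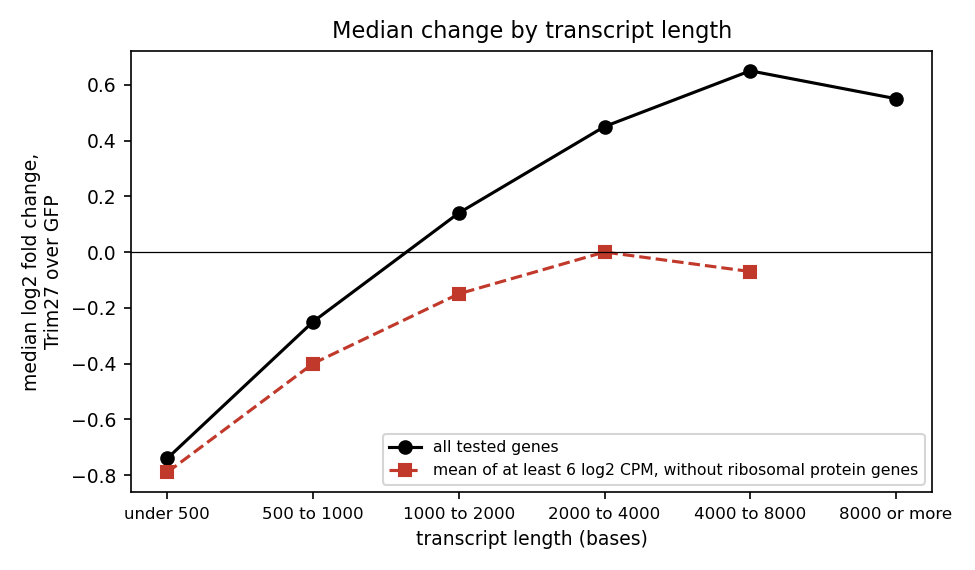
Median log2 fold change of Trim27 over GFP (vertical axis) for 6 classes of transcript length in bases (horizontal axis), for all tested genes with a length (circles) and for genes with a mean of at least 6 log2 CPM other than ribosomal protein genes (squares, classes of at least 20 genes). The median goes from -0.74 in the shortest class to 0.65 at 4000 to 8000 bases over all genes, and from -0.79 to -0.07 over the abundant ones.

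Among the myeloid transcription factors, 8 of 11 tested members rose, 2 fell and 1 did not pass (median log2 fold change 0.74). With the length trend removed 6 rose and 3 fell (median 0.42), and without Trim27 replicate 1, when 12 members were tested, 8 rose and 3 fell (median 0.45). Spi1, which encodes PU.1 and is needed for myeloid development, rose from 67.6 ± 3.31 to 120.0 ± 5.18 CPM (0.83, SE 0.06, adjusted p = 2.4e-13). Runx1, a regulator of definitive hematopoiesis, rose from 36.3 ± 2.43 to 78.0 ± 2.59 CPM (1.10, SE 0.07). Egr1, an immediate early factor linked to monocyte differentiation, rose from 34.7 ± 3.23 to 92.6 ± 4.97 CPM (1.41, SE 0.07). Irf8, a factor of monocytes, dendritic cells and B cells, rose from 1.5 ± 1.2 to 8.75 ± 1.03 CPM (2.57, SE 0.33), and among the GFP libraries it was highest in replicate 1 (3.20 CPM) and lowest in replicate 4 (0.206 CPM). Cebpe, a granulocyte factor, fell from 57.7 ± 6.29 to 33.3 ± 4.92 CPM (-0.80, SE 0.10), and Gfi1, a repressor of monocyte genes in granulocyte precursors, fell from 12.5 ± 1.37 to 5.58 ± 0.301 CPM (-1.16, SE 0.16). Cebpa, which drives entry into the granulocyte and monocyte lineage, was at 24.7 ± 0.874 CPM in the GFP group and 23.5 ± 1.49 CPM in the Trim27 group (-0.07, adjusted p = 0.482). That value was 0.23 (adjusted p = 0.0335) under library size alone and -0.56 (adjusted p = 6.5e-06) with the length trend removed. Klf4 had too few counts to be tested, with 2 counts over the GFP libraries and at most 3 in any Trim27 library. The list as a whole was not called by camera (adjusted p = 0.953).

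**Figure D3:**
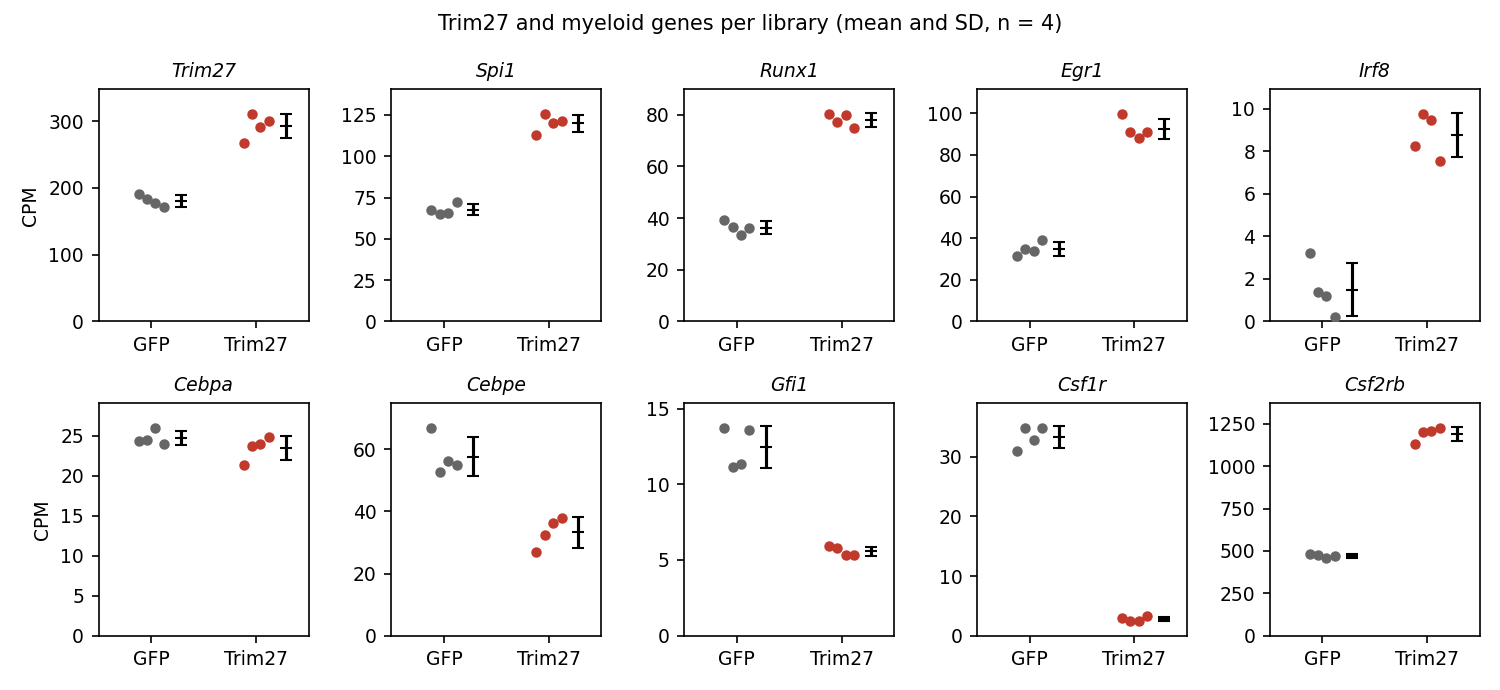
CPM (vertical axes, from 0) of Trim27 and 9 myeloid genes in the 4 GFP libraries (grey) and the 4 Trim27 libraries (red), with the mean and SD of each group beside the points. Spi1, Runx1, Egr1, Irf8 and Csf2rb are higher in every Trim27 library, Cebpe, Gfi1 and Csf1r are lower, and Cebpa overlaps.

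Myeloid cytokine receptors split, with 6 of 10 tested members up and 4 down. Csf2rb, the shared beta chain of the GM-CSF, IL-3 and IL-5 receptors, rose from 471.6 ± 10.5 to 1193 ± 40.8 CPM (1.34, SE 0.04), and its close paralog Csf2rb2 rose by 2.05 on the log2 scale, although reads may be shared between this pair. Csf3r, the G-CSF receptor, had no count in any GFP library and was at least 153-fold higher. Csf1r, the M-CSF receptor, fell from 33.3 ± 1.84 to 2.79 ± 0.399 CPM (-3.59, SE 0.14). It overlaps Hmgxb3 on the opposite strand.

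Genes of myeloid stages and lineages did not move one way. Of 12 primary granule genes, 4 rose, 6 fell and 2 did not pass, but 7 rose and 3 fell under library size alone, and 6 rose and 3 fell with the length trend of abundant genes removed. Prtn3, which encodes proteinase 3, fell by 0.75 on the log2 scale and Nkg7 fell too (-4.88), while Igsf6 was at least 164-fold higher and Prss57 rose by 5.82. Of 5 late neutrophil genes, S100a9 rose (0.54), Anxa1 fell (-0.80) and 3 did not pass, but 2 rose and 1 fell under library size alone and with the length trend removed, and 4 rose and 1 fell with the length trend of abundant genes removed. Of 8 monocyte genes, 5 rose, 2 fell and 1 did not pass. Lyz2, which encodes lysozyme, rose by 1.70 and Ctss, a lysosomal protease, by 2.79, while Ly6c2 fell (-4.77). Of 8 dendritic cell and MHC class II genes, 4 rose, 2 fell and 2 did not pass. Batf3 was at least 45.9-fold higher, H2-DMa was 63.5-fold higher (95% counting interval 21.6 to 309.7, with overlap of Brd2), and Zbtb46 (-2.92) and Cd74 (-2.48) fell. Of 14 tissue macrophage markers only 2 could be tested, and 11, among them C1qa, Mrc1, Marco and Cd163, had no count in any library. The 2 tested ones rose, Emr1, the gene of F4/80, by at least 130-fold and the iron exporter Slc40a1 by 322-fold (88.9 to 2660).

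Genes of other blood lineages also moved in both directions. Of 21 erythroid genes, 8 rose, 12 fell and 1 did not pass, but 9 rose and 9 fell under library size alone, and 10 of 20 rose and 7 fell with the length trend of abundant genes removed. Gata1, the main erythroid and megakaryocyte factor, rose from 166.9 ± 7.56 to 314.2 ± 14.9 CPM (0.91, SE 0.05), while Klf1 fell from 911.3 ± 20.96 to 502.4 ± 40.5 CPM (-0.86, SE 0.05). The embryonic globin Hbb-bh1 (-3.78) and the membrane skeleton gene Epb4.2 (-4.50) fell. Of 15 megakaryocyte genes, 6 rose, 5 fell and 4 did not pass, with 9 up and 4 down under library size alone, and 3 up and 9 down of 14 with the length trend removed. The platelet genes Gp9 (-1.46) and Pf4 (-1.09) fell, while Rab27b rose by 3.29 and G6b was at least 66.8-fold higher. Of 10 mast cell, basophil and eosinophil genes, 6 rose and 4 fell. The mast cell protease Cpa3 (1.32), the IgE receptor chain Ms4a2 (5.85) and Gata2 (0.66, but 0.05 with adjusted p = 0.401 when the length trend was removed) rose, and eosinophil peroxidase Epx fell (-1.91). Of 10 stem cell and multipotent progenitor genes, 4 rose, 5 fell and 1 did not pass, but 5 rose and 4 fell under library size alone. Cd34 (-1.05) and Ctla2a (-0.77) fell, Esam was lower by a ratio of 530 (95% counting interval 146 to 4389), and Meis1 rose by 5.38 from 8 counts over the GFP libraries.

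Of 10 B cell markers, 0 rose, 6 fell and 4 did not pass (median -1.28), and camera did not call the list (adjusted p = 0.576, and adjusted p = 0.957 with an estimated correlation). Dntt, the polymerase that adds bases at antigen receptor joints, fell from 16.3 ± 4.51 to 1.80 ± 0.213 CPM (-3.16, SE 0.21). The surrogate light chain genes Igll1 (-1.76) and Vpreb1 (-1.52, with overlap of Top3b) and the factor Ebf1 (-1.38, adjusted p = 0.00294) fell too, as did Cd79a and Il7r, which the naming rule did not choose. These markers varied between the GFP libraries, and 9 of the 10 were highest in GFP replicate 1. Without that library only Dntt, Igll1 and Vpreb1 fell, 7 markers did not pass and the median was -0.76, with Ebf1 at -0.78 (adjusted p = 0.0677). Without GFP replicate 4, 9 markers fell.

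Few T and NK cell, hepatocyte, endothelial and stromal markers were abundant enough to test. Of 2 T and NK cell markers, Lck fell (-3.77) and the granule protease Gzmb rose from 23.01 ± 5.08 to 112.0 ± 2.51 CPM (2.27). Both tested hepatocyte markers rose, alpha-fetoprotein (Afp) from 1.42 ± 0.239 to 9.25 ± 1.14 CPM (2.68) and Apoa1 by at least 73.7-fold. However, Alb, Ttr, Apob, Ahsg, Fga, Fgb, Serpina1a and Hnf4a had no count in any library. Apoa2 and Trf had counts in Trim27 libraries only, too few to be tested. Of 4 endothelial and stromal markers, Col1a2 (at least 22.6-fold higher) and Igfbp7 (at least 25.4-fold higher, with overlap of Polr2b) rose, and Pdgfrb (-3.03) and Dlk1 (-0.97, adjusted p = 0.0206) fell. Cdh5, Kdr, Col3a1, Sparc, Dcn and Lyve1 had no count in any library, and Col1a1 had 2 counts in GFP replicate 1 only. The Dlk1 call was lost under library size alone (-0.67), without GFP replicate 1 (-0.81) and without Trim27 replicate 1 (-0.82), among other settings.

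Members of the NF-kB, JAK-STAT and immediate early lists rose more often than they fell. Genes of low abundance did too, with 1238 rises and 489 falls under 2 log2 CPM and 1596 rises and 933 falls from 2 to 4. The list medians lay at or above those of 86.22% (NF-kB), 96.09% (JAK-STAT) and 98.92% (immediate early) of 10000 lists matched on abundance. Those matched lists treat genes as independent, and 22 lists were compared in this way. Of 13 NF-kB targets, 10 rose, 2 fell and 1 did not pass (median 1.95, camera adjusted p = 0.953). The subunit gene Nfkb2 (1.34, with overlap of Psd) and the adhesion gene Icam1 (97.3-fold higher, 95% counting interval 26.7 to 806.8) rose, while the inflammatory cytokine Il1b (-3.39) and the inhibitor Nfkbie (-3.22) fell. Of 13 JAK-STAT components and targets, 12 rose and 1 fell (median 1.02, camera adjusted p = 0.155), and with the length trend removed 9 rose and 2 fell (median 0.50). Oncostatin M (Osm) rose from 5.29 ± 1.18 to 36.7 ± 2.84 CPM (2.80) and Cish, a feedback inhibitor, from 59.9 ± 3.71 to 131.5 ± 4.38 CPM (1.14), while the adjacent and overlapping genes Stat5a (2.12) and Stat3 (1.02) also rose. Of 13 immediate early and heat shock genes, 9 rose, 1 fell and 3 did not pass (median 0.98, camera adjusted p = 0.155). With the length trend removed 7 rose and 4 fell. Among them the chaperone Hsp90aa1 rose by 1.32, the mRNA decay factor Zfp36 by 1.98 and the phosphatase Dusp1 by 5.57, which overlaps Ergic1. Interferon-stimulated genes split, with 5 of 9 up and 4 down, and with 4 up and 4 down when the length trend was removed. Oas1a (-2.56) and Bst2 (-1.11) fell, and Irf7 (137-fold, 95% counting interval 37.6 to 1132, with overlap of Phrf1) and Ifit2 (91.0-fold, 24.98 to 754.7) rose.

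Of 12 p53 targets, 6 rose, 5 fell and 1 did not pass. The counts were 8 up and 3 down under library size alone, and 4 up and 7 down with the length trend removed (median -0.37). The cell cycle inhibitor Cdkn1a rose from 41.3 ± 0.885 to 93.3 ± 5.68 CPM (1.18) and Pmaip1 was at least 104-fold higher, while the cell death gene Bax (-0.92) and Phlda3 (-1.08) fell. Of 15 unfolded protein and integrated stress response genes, 8 rose, 5 fell and 2 did not pass. The counts were 10 up and 2 down under library size alone, 9 up and 3 down with the length trend of abundant genes removed, and 6 up and 8 down with the length trend removed (median -0.11). Chac1, a target of the integrated stress response, fell from 59.0 ± 1.18 to 7.61 ± 0.460 CPM (-2.95), and the cystine transporter Slc7a11 (4.62), the disulfide isomerase Pdia4 (3.17) and Herpud1 (1.20) rose.

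Of 21 cell cycle genes, 12 rose, 7 fell and 2 did not pass (median 0.28). That median lay at or above those of 99.77% of 10000 lists matched on abundance, which treat genes as independent. The list was not called by camera (adjusted p = 0.957). The mitotic genes Top2a (50.9 ± 3.02 to 120.7 ± 3.66 CPM) and Plk1 (1.16) and the replication gene Mcm4 (0.70) rose, and Ccne1, the cyclin of the entry into S phase, fell (-1.25). With the length trend removed, 8 of these genes rose and 12 fell, and under library size alone 14 rose and 3 fell. Of 16 cholesterol synthesis genes, 7 rose, 7 fell and 2 did not pass, with 9 up and 3 down under library size alone, and 4 up and 10 down with the length trend removed. Dhcr7 (-1.76) and Mvd (-1.23) fell, and Lss (1.04) rose. Of 14 glycolysis genes, 5 rose, 4 fell and 5 did not pass, with 11 up and 1 down under library size alone, and 10 up and 2 down with the length trend of abundant genes removed. Without GFP replicate 1, 5 rose and 2 fell, and without Trim27 replicate 2, 4 rose and 5 fell. Pgk1 (0.58) and Hk1 (0.59, with overlap of Hk1os) rose, and Tpi1 (-0.53, with overlap of Spsb2) and Pfkl (-0.32) fell, although Pfkl was at -0.01 (adjusted p = 0.832) under library size alone.

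Of 84 ribosomal protein genes tested, 83 fell and only Rpl4 rose (0.12), with a median log2 fold change of -0.89, and 27 fell at least 2-fold. Rps19 fell from 8043 ± 63.8 to 3443 ± 130 CPM (-1.22, SE 0.04) and Rpl37a from 607.3 ± 22.3 to 221.1 ± 10.6 CPM (-1.46, SE 0.05). Rpl36 (-1.33) and Rpl38 (-1.31) fell as well. Reads of these genes may be shared with their many pseudogenes. Of the lists fixed in advance this was the only one called by camera (adjusted p = 7.7e-24), and it was not called with an estimated correlation (adjusted p = 0.153 with an estimated correlation). The median stayed below 0 under each scaling (-0.59 with library size alone), with the length trend removed (-0.65) and with the length trend of abundant genes removed (-0.39). Of 11 mitochondrially encoded genes, 2 rose, 4 fell and 5 did not pass, but 3 rose and 2 fell under library size alone, and 4 rose and 1 fell with the length trend of abundant genes removed. The complex I gene mt-Nd5 (-0.82, with overlap of mt-Nd6) and mt-Co3 (-0.71, with overlap of mt-Atp6) fell, and mt-Nd4 (0.35) and mt-Cytb (0.31) rose. The mt-Co3 call was lost with the length trend of abundant genes removed (-0.34, adjusted p = 0.0771).

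**Figure D4:**
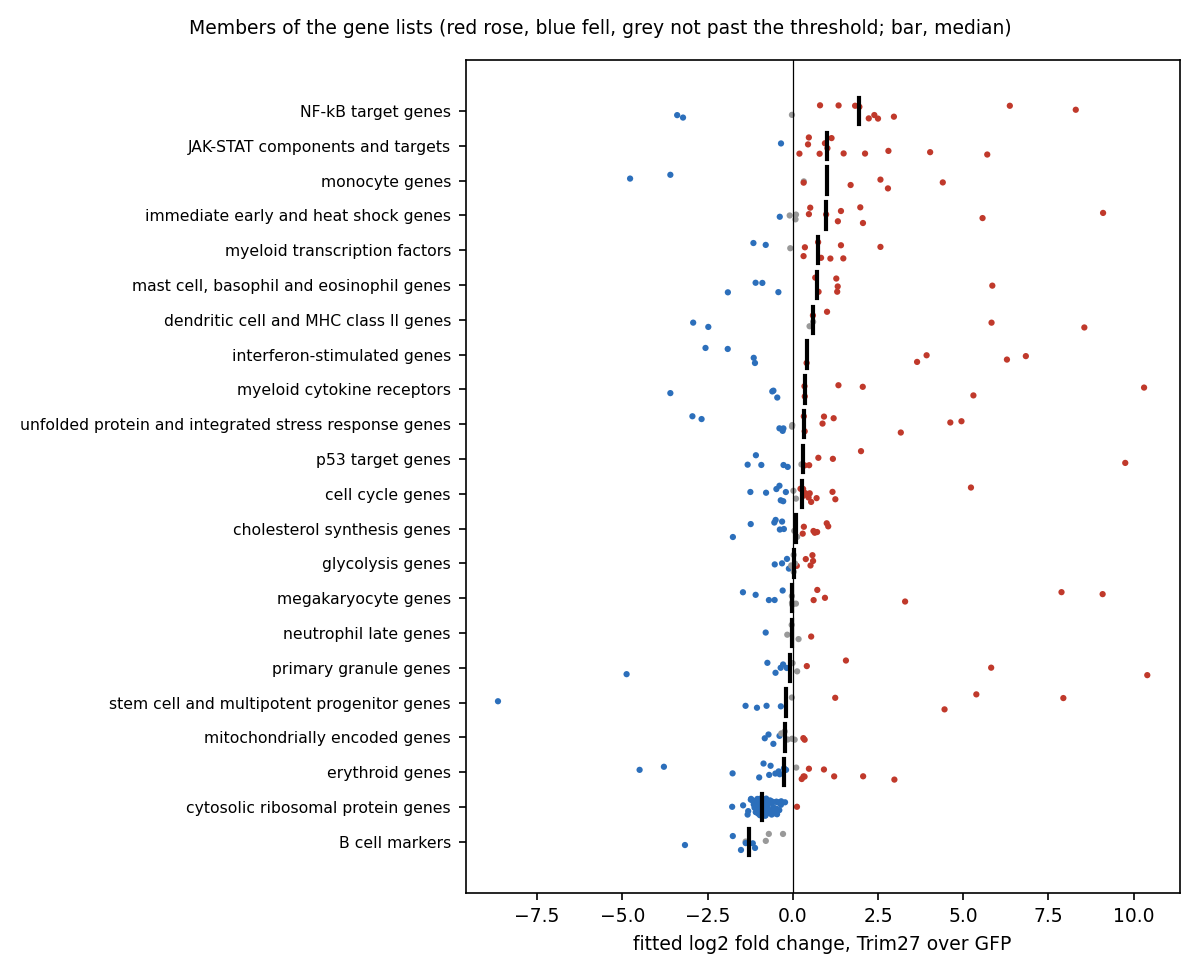
Fitted log2 fold change of Trim27 over GFP (horizontal axis) of each tested member of the 22 lists with at least 5 tested members (vertical axis), with genes that rose in red, genes that fell in blue, genes not past the threshold in grey and the median of each list as a black bar. The 84 ribosomal protein genes form a compact group around -0.89, while most other lists spread to both sides of 0, and with library size alone the medians of the primary granule, late neutrophil, megakaryocyte, stem cell, mitochondrially encoded and erythroid lists lie above 0.

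Counts adjusted over the list alone were the same in each of the 26 lists. Median, mean and camera direction differed in sign for the primary granule, monocyte, dendritic cell, megakaryocyte, mast cell, stem cell, interferon, cholesterol and glycolysis lists. Placing genes without counts at their bound left the median of each camera-tested list unchanged. Counts of genes that overlap a neighbour are uncertain, because the strand setting of the counting is not given in the sources used here.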

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

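The tests of depth, of the B cell markers and of the spread at low abundance were chosen after their results were seen, and the other tests in this part were set down before.

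Genes listed in 1 group only were the most unusual feature of the comparison, with 532 absent from all GFP libraries and 101 absent from all Trim27 libraries. Depth alone would leave an expected 2.22e-05 tested genes or fewer absent from a group, a value kept low by the filter on counts, so it is a poor account of these genes. Over all 15097 genes with counts, without the filter, 2.04 to 2.32 times as many were absent from the GFP group and 1.32 to 1.55 times as many from the Trim27 group as depth alone would leave. Depth and other losses cannot be told apart there, because the test did not decide for both groups. Loss in single libraries was not seen, since 0 gene and library pairs were at 0 where the other 3 libraries averaged at least 50 counts, against 336 genes absent from all 4 libraries at that level. Loss of transcripts before the 4 libraries of a group were split and transcription switched by the Trim27 virus cannot be told apart for these genes, because 0 of 357 tested members of ubiquitous complexes were absent where only 2.6 were expected, a ratio of 0 with an upper limit of 1.42. The wide spread at low abundance may come from few starting transcripts sampled before the libraries were split, but the test cannot decide this. Members of ubiquitous complexes spread at least 0.72 times as widely as other genes of their abundance in classes with at least 20 members. From 2 to 4 log2 CPM their SD was 2.51 against 3.48. At 8 log2 CPM or more it was 0.45 against 0.57, so genes with many transcripts gave a similar result. Under 2 log2 CPM only 3 members were tested, with an SD of 2.48 against 4.26. A response of the cells to Trim27 stays open for the same genes.

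The median fall of the ribosomal protein genes was larger than that of lists of other genes matched on length and abundance, but it was not particular to them. Among families chosen after the data were seen, complex I and cytochrome c oxidase subunits had medians of -0.86 and ATP synthase subunits -0.74, while other families fell less or rose. Abundant genes under 500 bases other than ribosomal protein genes had a median of -0.79. Of the 10000 matched lists, 0% had a median as low as -0.89, the lowest being -0.71 and their median -0.36. By median annotated lengths, a general fall of short transcripts would then not be the whole of the fall. The matched lists treat genes as independent, and the lengths of the transcripts expressed in these cells were not measured. Scaling did not account for it either, because the median was still -0.59 under the scaling that raised it most. A difference in RNA quality or library preparation between the groups was not tested, and an effect of Trim27 on these transcripts stays open as untested.

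Of 10 tested B cell markers, 6 fell with the Trim27 virus and 4 did not pass, and camera did not call the list (adjusted p = 0.576). Random gains and losses at this abundance cannot be told apart from other explanations, because the list was picked for its low median (-1.28) among 22 lists. Of 10000 lists matched on abundance 0.32% had a median as low, which is 7.04% when multiplied by the number of lists, and the matched lists treat genes as independent. A smaller share of B-lineage cells in the sort may account for part of the falls. A myeloid progenitor gate would, however, be meant to exclude such cells. Of the markers 100% lay below 0, with an SD of 0.78 against 3.65 in matched lists. Their falls were unequal, with Dntt at -3.16 (SE 0.21), Igll1 at -1.76 (SE 0.15) and 4 markers not past the threshold. A like dilution of all 10 markers would not give such a range by itself. B-lineage material that differed from library to library is another candidate explanation, because the markers varied within groups with a median chi-square per degree of freedom of 9.02 against 2.19 in matched lists, and 0% of 10000 matched lists were as variable. Without GFP replicate 1, where 9 of the 10 were highest among GFP libraries, the falls of Dntt, Igll1 and Vpreb1 remained and the median was -0.76.

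A sample far from the other 3 of its group was found in 16 of 226 groups tested, where chance gives about 11.3, by the gap to the nearest library divided by the range of the group. In the Trim27 group, replicate 1 stood apart for Plek2 (ratio 0.848, 22.98 CPM against 17.7 to 18.5), Klf1 (0.867, 442.1 against 517.9 to 529.5), Cdkn1a (0.878, 84.8 against 95.4 to 96.8) and Lss (0.896, 240.8 against 262.5 to 265.1). In the GFP group, replicate 1 was high for Cd74 (0.875, 16.7 against 12.7 to 13.2) and Hk1 (0.978, 112.3 against 94.9 to 95.3), and replicate 4 was low for Hfe (0.865, 18.3 against 21.5 to 22.0) and Cdkn1a (0.857, 40 against 41.6 to 41.9). A ratio of 1 came from genes with counts in 1 library of the group, namely Depdc7, Aldh1l1 and Esam in the Trim27 group and Prss57, Slc40a1, Irf7, Ifit2 and Icam1 in the GFP group.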

How the results depend on the processing

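The setting that kept only abundant genes, those that removed a length trend and the halved counts were chosen after seeing the data. The count of 9442 genes past the threshold was 9352 to 9529 when 1 library was left out, with 5100 to 5351 rises and 4118 to 4334 falls, and 8834 to 10382 under the other scalings, tools, length settings, halved counts (8973) and no filter. With the length trend removed, falls (4749) outnumbered rises (4243). Fewer genes entered some settings, with 2287 past the threshold (1133 rises, 1154 falls) of 2653 abundant genes and 6715 under the strict filter (3453 rises, 3262 falls), and a fold above 1.5 left 6344 (3892 rises, 2452 falls). The numbers of the replicates did not pair the libraries, with correlations of deviations of -0.012, -0.035, 0.021 and 0.009 for the same number and up to 0.076 for others, and no GFP library matched its own number best except replicate 3. With the replicate block 9160 genes passed, 9153 of them shared with the main result. Trim27 was 0.63 to 0.72 when 1 library was left out and 0.09 with the length trend removed, up to 1.0 under library size alone, and the cause was not tested. Cebpa turned to 0.23 under library size alone, whose median of all genes was 0.44. Other named genes kept their direction wherever it was called, and calls were lost for Dlk1, Ebf1, Pfkl, Gata2 and mt-Co3 in some settings. The ribosomal protein list was called in each setting except camera with an estimated correlation (adjusted p = 0.153), with 5.8e-26 to 1.6e-22 when 1 library was left out. No other list was called by camera in any setting. The fry test called 17 of the 22 lists, the ribosomal protein list among them. A call by it does not set a list apart from other genes, because 85.53% of all tested genes passed the threshold. With fry, which tests a list by itself, lists were called up for primary granule genes (adjusted p = 0.0123) and monocyte genes (0.0123), megakaryocyte genes (0.0076) and mast cell genes (0.00823), against camera's direction, and in camera's direction for myeloid factors (5.4e-05), cytokine receptors (8.5e-06), erythroid genes (1.8e-04), stem cell genes (0.00269), B cell markers (0.0119), interferon genes (0.0123), NF-kB (5.5e-04), JAK-STAT (7.6e-08), cell cycle (8.5e-06), p53 (0.00653), immediate early (8.3e-08) and stress response genes (9.6e-07). Depth limited genes of few counts, with a median SE of 0.46 on the log2 scale under 2 log2 CPM against 0.04 at 10 or more. The 0.46 may be too low, because 487 genes under 2 log2 CPM had no count in 1 group.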

Other observations

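The tests of gene families here were chosen after the data were seen. Of 36 nuclear-encoded complex I subunits, 30 fell and 1 rose (median log2 fold change -0.86, camera adjusted p = 1.3e-09, adjusted p = 0.00842 with an estimated correlation). Of 16 ATP synthase subunits 12 fell (median -0.74), and of 11 cytochrome c oxidase subunits 9 fell (median -0.86). Mitochondrial ribosomal proteins fell for 57 of 73 members (median -0.56, camera adjusted p = 1.4e-07, adjusted p = 0.00371 with an estimated correlation), and the Sm and LSm proteins of the splicing machinery for 19 of 22 (median -0.53). These medians stayed below 0 under library size alone (-0.56, -0.44, -0.56, -0.25 and -0.22 in the same order) and with the length trend of abundant genes removed (-0.30, -0.27, -0.26, -0.24 and -0.32).

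Other large complexes varied. Nucleoporins rose for 14 of 19 members (median 0.81, camera adjusted p = 0.0309, adjusted p = 0.163 with an estimated correlation), with a median of 0.22 when the length trend was removed. Proteasome subunits fell for 22 of 37 (median -0.21, camera adjusted p = 0.0291, adjusted p = 0.0563 with an estimated correlation), but their median was 0.09 under library size alone. Aminoacyl-tRNA synthetases were split, with 15 up and 15 down. Kinesins (12 of 21 up), zinc finger genes of the Zfp series (106 of 191 up) and chaperonin subunits (6 of 8 up) were not called by camera as families.

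Chance in how these 8 libraries fall into groups is an unlikely source of the number of changed genes. Of the 35 splits of the 8 libraries into equal groups, only 1, the real one, gave as many genes. The real split gave 9442 and the highest of the others 0. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the groups, which widens the spread within each side, so few calls were likely there. The split count says that the libraries of the groups differ, not why, and it does not exclude chance before the libraries of a group were made.

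Neighbouring genes moved together slightly. Over 9221 neighbouring pairs without overlap, the correlation across genes of log2 fold changes scaled within abundance classes was 0.045, above the highest of 1000 shuffles of the gene order (0.033), and it was 0.038 after trends with length and GC content were removed (highest shuffle 0.030). It was 0.062 for pairs under 10 kb apart (1 of 1000 shuffles as high), 0.034 at 10 to 100 kb (23 of 1000) and 0.039 at 100 kb or more (23 of 1000). A correlation of this size leaves nearly all of the variation unexplained.

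Transcripts of both sexes were present in each library, with 70 to 114 counts of Xist and 19 to 79 counts of the Y-linked gene Ddx3y. Uty, another Y-linked gene, had no count in any GFP library and 6 to 12 counts in the Trim27 libraries.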
